A study of Mus musculus with 24 samples.

How the data were processed

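Gene expression was measured in CD31+ cells sorted from wild-type and Scl-/- mouse embryos at stage E9.25. Scl, gene symbol Tal1, encodes a basic helix-loop-helix transcription factor needed for the formation of blood cells. CD31 (Pecam1) marks endothelial cells and part of the blood lineage, CD41 (Itga2b) together with c-kit (Kit) marks early blood progenitors, and Pdgfra marks mesenchymal and cardiogenic cells. The 24 arrays fall into 12 groups of 2, which the series design calls biological duplicates. The design also states that they belong to 3 separate experiments, without saying which array belongs to which. Groups and replicate numbers were taken from the sample titles. For the arrays titled Pdgfra+, the cell type field of the labels reads Pdgfra-, while the title and the source name read Pdgfra+. The title was followed.

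Per the labels' protocols, total RNA was isolated with the RNeasy Micro Kit, amplified with a NuGEN Pico kit and hybridised to a mouse Affymetrix array after biotin labelling. The submitters' processing notes name RMA, affy and limma, with no versions or roles. The deposited table holds 1 column per array and 45101 probe sets, of which 64 are control probe sets. No raw scanner files were used here.

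The deposited columns are on 2 scales. In the 6 columns of the yolk sac arrays sorted on Pdgfra, the deposited values are log2 expression values, with medians of 3.82 to 3.97 and maxima of 14.5 to 14.7. In the other 18 columns the deposited values are exponentials of such values, with a maximum of 3269017 in the heart columns and 2908513 in the CD31+ and placenta columns. For the 8 heart columns the base is settled by the rounding of the values: their natural log lies on a grid of 3 significant digits in 51.2% of the probe sets, within a tolerance of 1e-05, and their log2 in 0%. For the 10 columns of CD31+ and CD41+ cells of the yolk sac and of the placenta no such grid exists. There the base was inferred. The natural log gives maxima of 14.65 to 14.88 and a spread over probe sets 1.03 times that of the Pdgfra-sorted yolk sac columns, against 1.49 times with log2. With log2 the maxima would be 21.14 to 21.47, above the 16 bits of the scanner, which argues against base 2. All 18 columns were therefore transformed with the natural log and the result treated as log2 expression. If the base of the 10 columns were 2, their log2 fold changes would be 1.44 times as large. Array medians were 3.82 to 3.97 in the Pdgfra-sorted yolk sac, 4.24 to 4.38 in the heart and 5.46 to 5.54 in the CD31+ yolk sac and placenta columns. The 3 sets were evidently normalized separately, so levels were compared only within a set. No array gives a depth, and the number of arrays limits the precision.

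Probe sets were named through the platform annotation provided with the table, with symbols checked against the RefSeq gene table by gene identifier (34754 probe sets matched and 0 symbols changed). Of the 45101 probe sets, 34958 have 1 gene symbol, 932 have several and 9211 were not named here. Only probe sets with 1 symbol were used. Each of 18193 genes was represented by its probe set with the highest mean over the 24 arrays, and 9010 genes have more than 1 probe set.

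Tests were made with limma 3.58.1 in R 4.3.3. The fit has 12 group means and all 24 arrays, with 12 residual degrees of freedom and 3.15 prior degrees of freedom, and gives 10 contrasts and 3 interactions. All p-values are two-sided. Adjusted p-values are limma's moderated p-values after Benjamini-Hochberg adjustment over the 18193 genes, and a gene was called at an adjusted p under 0.05. The test assumes 1 spread for a gene in all sets. The sets differ: the SD between duplicates, pooled over genes, was 0.25 to 0.39 in the yolk sac CD31+ and CD41+ groups, 0.59 to 0.73 in placenta, 0.62 to 0.77 in the Pdgfra-sorted yolk sac and 0.76 to 0.99 in the heart. Counts from a fit of the arrays of the same set alone (6 yolk sac CD31+ and CD41+, 4 placenta, 6 Pdgfra-sorted yolk sac or 8 heart arrays) are therefore printed beside those of all 24 arrays.

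Both fits were tested on simulated arrays of the 18193 genes, with 200 genes changed by 1, 2 or 4 on the log2 scale. Group means were the real ones, except that the 2 groups compared were first given their common mean. The heart and the Pdgfra-sorted yolk sac each kept their own spread. The yolk sac CD31+ and CD41+ arrays shared 1 spread with placenta. Results for yolk sac CD31+ cells thus rest on a spread taken partly from the noisier placenta arrays, and describe these cells only roughly. For yolk sac CD31+ cells by genotype, the fit of all 24 arrays recovered 32.8% of the changes of 2 and 89.4% of the changes of 4, and 3.6% of the called genes were unchanged. For the same comparison in Pdgfra- yolk sac cells, 25.4% of the called genes were unchanged. For Pdgfra+ and Pdgfra- heart cells by genotype this share was 56.5% and 58.3%, against 2.8% and 4.3% with the heart arrays alone, which in turn recovered 51.5% and 65.2% of the changes of 4. Single-gene calls in the heart and in the Pdgfra-sorted yolk sac thus rest on a spread taken partly from quieter arrays. The shares of unchanged genes depend on the 200 changed genes chosen and need not hold for the real calls. For Pdgfra- heart cells by genotype 155 unchanged simulated genes were called, while the real data gave 88 called genes in all.

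24 gene lists were written from textbook knowledge before the data were examined, with the series title in mind, and tested with camera at a preset inter-gene correlation of 0.01. In 2 lists a written member without a probe set here was read as another gene that shares its name as a synonym: Hcn4 as Hcn3 in the cardiac excitation and metabolism list and Trf as Trh in the visceral endoderm list. Without these 2 members, a check added after the data were seen, 0 of the 240 tests changed their call with either correlation. All 240 tests of lists were adjusted together. Each was repeated with an estimated correlation, which asks for more evidence when the members of a list vary together, and with fry, which tests whether a list moves 1 way on balance. At the preset correlation 101 of the 240 tests passed, and 52 of these passed with the estimated correlation. Where a call is lost with the estimated correlation, that adjusted p is given. Counts of list members "adjusted over the list alone" use Benjamini-Hochberg adjustment within the list.

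The genes named are, for each contrast, the 5 largest rises and 5 largest falls among called genes with an assigned symbol whose 2 arrays in 1 group both lie above those of the other, up to 4 members with the largest absolute change of each list described, and Tal1, Pecam1, Pdgfra, Itga2b and Kit. For each interaction they are the 5 largest estimates in each direction. The tests, lists, rule and the following alternative settings were fixed before the data were examined: quantile and cyclic loess normalization, centring on the median of 13 housekeeping genes, the arrays of the same set, a mean-variance trend with a robust prior, the mean of all probe sets of a gene, a filter on dim genes that left 14196, the replicate number as a block, a fold threshold of 2, and leaving out each array in turn. A group left with 1 array is assumed to vary like the other groups. The count of called genes can then rise, and many of the genes are not those of the main fit. A higher count without an array is therefore no sign of stability. Values are means of log2 expression ± SD, and fold changes are log2 differences ± SE from the fit of all 24 arrays, with n = 2 arrays per group.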

Results

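The series compares CD31+ cells of the yolk sac, placenta and heart between wild-type and Scl-/- mouse embryos at stage E9.25, as its title states, to ask how Scl bears on cardiomyogenesis in prospective hemogenic endothelium and endocardium. Each of the 12 groups has 2 arrays. They are CD31+ cells of the yolk sac and of the placenta from both genotypes, CD41+ c-kit+ cells of the wild-type yolk sac, CD31+ yolk sac cells sorted further on Pdgfra (wild-type Pdgfra-, Scl-/- Pdgfra- and Scl-/- Pdgfra+), and CD31+ heart cells of both genotypes sorted as Pdgfra+ and Pdgfra-. Duplicates correlated at 0.980 to 0.992 in the yolk sac CD31+ and CD41+ groups, 0.928 and 0.949 in placenta, 0.909 to 0.946 in the Pdgfra-sorted yolk sac and 0.866 to 0.930 in the heart.

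The target gene was examined first, as a check on the labels. Tal1 was 3.24 and 2.91 in the Scl-/- yolk sac CD31+ arrays against 7.47 and 7.87 in wild type, and 5.32 and 5.06 in Scl-/- placenta against 7.32 and 7.89. In the heart the transcript went against the labels. It was 7.94 in replicate 1 of the Pdgfra+ cells and 6.61 in replicate 2 of the Pdgfra- cells labelled Scl-/-, against 5.44 to 6.99 in the 4 wild-type heart arrays, while the other 2 arrays labelled Scl-/- had 3.68 and 4.71. In the Pdgfra-sorted yolk sac it was 4.61 and 6.19 in wild type, 4.22 and 3.86 in Scl-/- Pdgfra- and 4.15 and 3.42 in Scl-/- Pdgfra+ cells, and in wild-type CD41+ c-kit+ cells 8.32 and 8.28. Tal1 passed the test in yolk sac CD31+ cells alone. Whether the Tal1 probe set lies in the deleted part of the gene is not given in the sources used here. Heart libraries are therefore called libraries labelled Scl-/-. Pdgfra, the gate gene, was 9.76 and 9.42 in Scl-/- yolk sac Pdgfra+ cells, 5.59 and 7.49 in Scl-/- Pdgfra- cells and 2.08 and 3.59 in wild-type Pdgfra- cells. In the heart it was 8.18 to 8.74 in the 4 Pdgfra+ arrays. In the Pdgfra- heart arrays it was 7.69 and 6.49 in those labelled Scl-/- and 5.68 and 3.84 in wild type. Pecam1 did not pass the test in any of the 10 contrasts, with changes from -1.53 to 1.09. Xist, the transcript of the inactive X chromosome, was 3.38 to 3.80 in the 4 heart arrays labelled Scl-/- and 9.07 to 11.82 in the 4 wild-type heart arrays, while Kdm5d, a gene of the Y chromosome, was 8.48 to 11.20 and 5.78 to 8.15. The mix of male and female embryos thus differed with the genotype label in the heart.

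**Figure D1:**
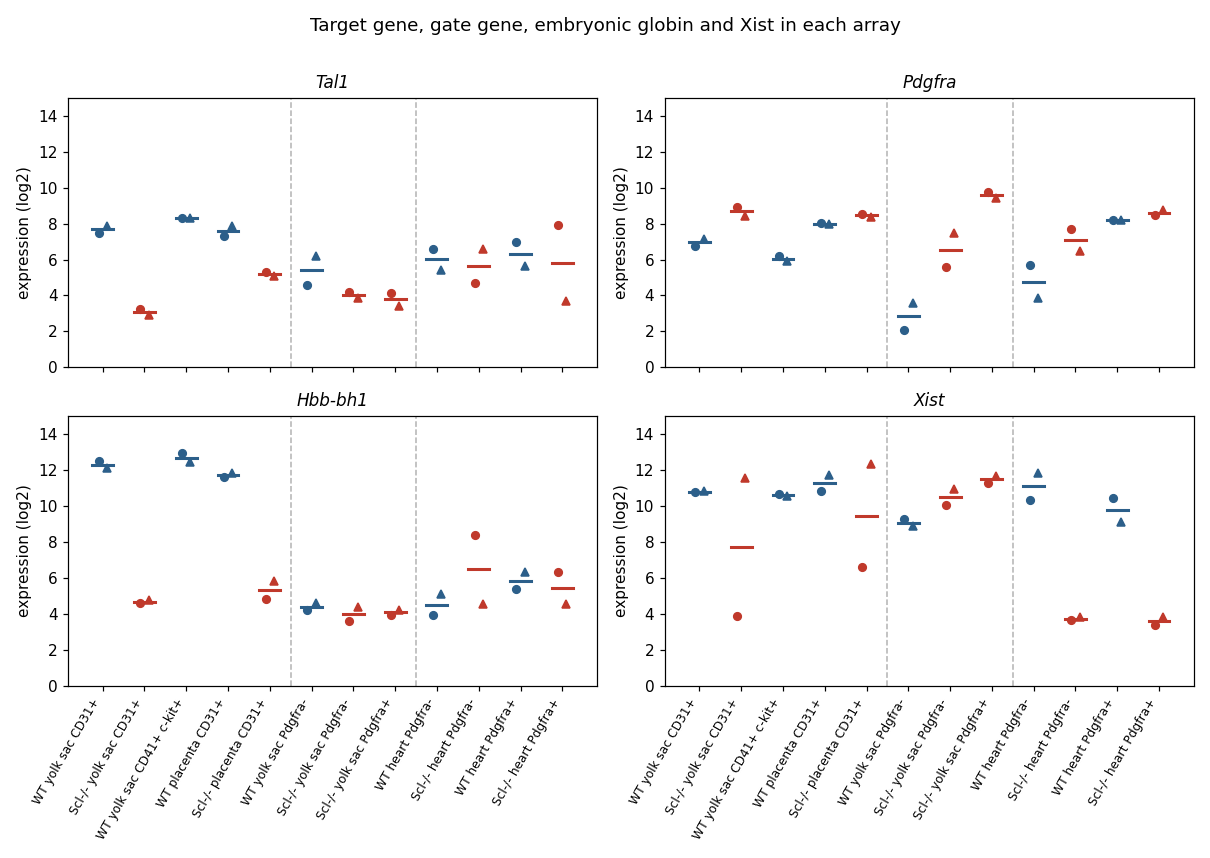
Expression (log2, vertical axes) of Tal1, Pdgfra, Hbb-bh1 and Xist in the 24 arrays, with circles for replicate 1, triangles for replicate 2, bars for group means, blue for wild type, red for Scl-/-, and dashed lines between the 3 separately normalized sets. Tal1 is low in both Scl-/- yolk sac CD31+ arrays (3.24 and 2.91) but reaches 7.94 in a heart array labelled Scl-/-, and Xist is under 4 in all 4 heart arrays labelled Scl-/-.

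In yolk sac CD31+ cells, blood cell transcripts were lower and transcripts of heart muscle higher in Scl-/- embryos. The sort holds part of the blood lineage. For the blood transcripts, a smaller share of blood cells and a lower level per cell cannot be told apart. The largest falls were of the embryonic globins Hbb-y (log2 fold change -10.89 ± 1.87), Hba-x (-8.34 ± 0.45) and Hbb-bh1 (-7.62 ± 0.88), of Mpo, the myeloperoxidase of granulocytes (-8.54 ± 1.01), and of Ptprc, the common leukocyte antigen (-7.38 ± 0.95). Hbb-bh1, for example, went from 12.27 ± 0.28 to 4.65 ± 0.11. The largest rises were of Myl7, the atrial myosin light chain (5.89 ± 0.71, from 5.25 ± 0.66 to 11.14 ± 0.73), Myh7, a cardiac myosin heavy chain (5.36 ± 1.03), Myocd, the muscle coactivator myocardin (5.35 ± 0.96), Tnnt2, cardiac troponin T (4.87 ± 0.91), and Kcnj8, a potassium channel subunit (4.66 ± 0.55). Their adjusted p-values lay between 1.37e-07 and 0.0207. Tal1 itself fell by 4.60 ± 1.0 (adjusted p = 0.0453, and 0.000544 in the fit of the 6 yolk sac arrays alone).

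Lists of blood genes fell together in these cells. Of 19 pan-hematopoietic surface and signaling genes, 10 fell, 0 rose and 14 fell when adjusted over the list alone (median -3.14, camera adjusted p = 4.72e-53), led by Ptprc, Coro1a (-6.41 ± 0.78) and Spn (-5.48 ± 0.60). Hematopoietic transcription factors fell in 8 of 23 cases (12 adjusted over the list alone, median -1.77, adjusted p = 1.27e-29), among them Myb (-6.03 ± 1.25), Gfi1 (-4.01 ± 0.75) and Gfi1b (-3.98 ± 0.48). Of 19 myeloid genes 8 fell (9 adjusted over the list alone, median -1.31, adjusted p = 5.92e-27), including Tyrobp (-6.69 ± 0.52) and Fcer1g (-4.36 ± 0.41). Of 18 erythroid genes 6 fell (9 adjusted over the list alone, median -1.35, adjusted p = 9.76e-24), Slc4a1, the red cell anion exchanger, by 4.35 ± 0.45. The megakaryocyte and platelet list was lower too, with 1 of 13 genes past the test, Plek (-6.66 ± 1.16), 5 adjusted over the list alone, a median of -0.60 and an adjusted p of 5.52e-11.

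The cardiac sarcomere list was higher, with 5 of 22 genes up and 0 down (11 up adjusted over the list alone, median 2.16, adjusted p = 2.33e-22). Myh6 had a change of 6.97 ± 1.80 that did not pass the test. Cardiac transcription factors were higher as a list (median 0.68, adjusted p = 1.70e-05), with Myocd past the test (3 of 19 adjusted over the list alone) and Hopx at 2.98 ± 0.70. So was the cardiac excitation and metabolism list (median 0.49, adjusted p = 0.00176), where Ryr2, the calcium release channel of heart muscle, rose by 1.76 ± 0.37 (1 of 19 genes, also adjusted over the list alone). With 0 members past the test over all genes, the lists of extracellular matrix (median 0.71, adjusted p = 5.51e-06), epithelial-mesenchymal transition and cushion (0.80, 5.49e-05) and lateral plate mesoderm (0.33, 0.00129) also shifted up. Those 11 lists held with the estimated correlation. The other 7 calls did not: yolk sac visceral endoderm (median -1.03, adjusted p = 0.0959 with the estimated correlation), pan-endothelial (-0.20, 0.211), epithelial (-0.71, 0.508), smooth muscle (0.36, 0.135), immediate early genes (-0.06, 0.371), cell cycle (-0.24, 0.178) and p53 targets (-0.19, 0.0958).

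In all, limma called 135 genes in yolk sac CD31+ cells, 21 higher and 114 lower in Scl-/-. The fit of the 6 yolk sac arrays alone called 481 (134 higher and 347 lower), 125 of them shared. Leaving out an array gave 69 genes without wild-type replicate 1, 50 without wild-type replicate 2, 70 without Scl-/- replicate 1 and 63 without Scl-/- replicate 2. Myl7, Kcnj8, Mpo, Hba-x, Hbb-bh1 and Ptprc kept their call in each. Fold changes in the yolk sac CD31+, CD41+ and placenta columns rest on the inferred base of the deposited values. Base 2, which the maxima of these columns argue against, would make these fold changes 1.44 times as large.

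In placenta CD31+ cells 2 embryonic globins, Hba-x and Hbb-bh1, were lower in Scl-/- embryos, and 3 other genes passed the test. Here too a smaller share of blood cells and a lower level per cell cannot be told apart. Hba-x changed by -7.51 ± 0.45 (adjusted p = 6.24e-07), Hbb-bh1 by -6.39 ± 0.88 (0.0118), Hemgn, a nuclear protein of blood cells, by -5.19 ± 0.39 (7.00e-06) and Gpr65, a proton-sensing receptor, by -2.72 ± 0.39 (0.0169). Hbb-y had a change of -10.57 ± 1.87 that did not pass the test (adjusted p = 0.0824). Robo2, an axon guidance receptor, was higher by 2.80 ± 0.33 (0.00197). Tal1 changed by -2.42 ± 1.0 (from 7.60 ± 0.40 to 5.19 ± 0.18) and did not pass the test (adjusted p = 1). Its spread is shared with the heart arrays, with an SD of 3.01 in Pdgfra+ cells labelled Scl-/-. In the fit of the 4 placenta arrays alone it did not pass either (adjusted p = 0.858). The pan-endothelial list was lower, with 0 of 22 genes past the test over all genes and 5 adjusted over the list alone (median -1.08, adjusted p = 7.74e-16). Its largest changes were those of Lyve1 (-3.55 ± 1.09), Sox18 (-2.21 ± 0.98) and Icam2 (-1.86 ± 0.44). Of the erythroid genes 2 of 18 were lower (4 adjusted over the list alone, median -0.66, adjusted p = 1.55e-11). The pan-hematopoietic (median -0.70, adjusted p = 3.64e-09), myeloid (-0.79, 1.97e-06), hematopoietic transcription factor (-0.48, 0.000631) and trophoblast lists (-0.88, 0.000694) were lower with 0 members past the test, trophoblast led by Prl4a1 (-2.26 ± 0.43). These 6 lists held with the estimated correlation. The last 4 were not called without wild-type replicate 1, nor the transcription factors without Scl-/- replicate 1. The arterial (median -0.50, adjusted p = 0.109 with the estimated correlation), epithelial-mesenchymal transition (0.46, 0.168) and visceral endoderm lists (-0.24, 0.508) lost their calls with that correlation. None of the 3 cardiac lists was called.

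The 5 placental genes, 1 higher and 4 lower, compare with 3 in the fit of the 4 placenta arrays alone (0 higher and 3 lower), and 2 are shared, Hba-x and Hbb-bh1. Without wild-type replicate 1 there were 63 genes, without wild-type replicate 2 there were 25, without Scl-/- replicate 1 there were 23 and without Scl-/- replicate 2 there were 8. Robo2, Hba-x and Hemgn kept their call in each, and Hbb-bh1 and Gpr65 did not. All 4 genes lower in placenta were also lower in yolk sac CD31+ cells, and 0 genes were higher in both. Independent lists would share 0, but both contrasts use the same spread of a gene, so their calls are not independent. Across the 18193 genes, which are not independent replicates, the fold changes of the 2 tissues correlated with Pearson's r of 0.25 and Spearman's rho of 0.16. The effect of genotype differed between the tissues for 10 genes, 3 with a higher value in yolk sac and 7 with a lower one. With the 10 yolk sac and placenta arrays alone there were 7. Their split was the opposite, 6 higher and 1 lower.

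Wild-type CD41+ c-kit+ yolk sac cells were compared with wild-type CD31+ yolk sac cells to set blood progenitors against a sort that also holds endothelium. Transcripts of matrix and endothelium were far lower in the progenitors. Lum, the matrix proteoglycan lumican, changed by -6.92 ± 1.12, Synpo, an actin-associated protein, by -6.60 ± 1.14 (1 of its 2 probe sets), Tmem204, a membrane protein of endothelium, by -6.42 ± 0.95, Smarca1, a chromatin remodeller, by -6.34 ± 1.04 and Clec14a, an endothelial lectin, by -6.33 ± 0.83. Higher were Hoxd1 (3.46 ± 0.59), the platelet tubulin Tubb1 (2.73 ± 0.33), the erythroid and megakaryocytic factor Gata1 (2.63 ± 0.33), the mucin Muc13 (2.57 ± 0.41) and the nuclear envelope protein Syne3 (2.56 ± 0.37). Adjusted p-values of these 10 genes ran from 0.000244 to 0.0044. Itga2b (1.11 ± 0.48) and Kit (0.50 ± 0.44), the genes of the gate, did not pass the test. With the 6 arrays alone Itga2b passed (adjusted p = 0.0275) and Kit did not (0.263).

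Of 17 matrix genes 12 were lower (14 adjusted over the list alone, median -3.45, adjusted p = 1.31e-35), for example Col3a1 (-6.27 ± 1.15) and Col1a2 (-5.43 ± 0.65). Pan-endothelial genes were lower in 9 of 22 cases (13 adjusted over the list alone, median -1.68, adjusted p = 7.69e-25), led by Cldn5 (-5.13 ± 0.82) and Cdh5 (-3.63 ± 0.39). Venous and lymphatic genes were lower in 7 of 10 cases (8 adjusted over the list alone, median -3.24, adjusted p = 2.69e-20), as with Stab2 (-4.90 ± 0.70) and Aplnr (-4.79 ± 0.74). Endocardial genes were lower in 4 of 13 cases (5 adjusted over the list alone, median -0.94, adjusted p = 1.97e-11), including Tbx20 (-6.11 ± 0.33), which also stands in the cardiac transcription factor list (1 of 19 lower, 4 adjusted over the list alone, median -0.34, adjusted p = 0.000118). Cushion genes (5 of 20 lower, 8 adjusted over the list alone, median -1.07, adjusted p = 6.43e-11), arterial genes (3 of 18, 7 adjusted over the list alone, -1.18, 1.41e-10), smooth muscle genes (2 of 12, 4 adjusted over the list alone, -0.44, 0.000163) and visceral endoderm genes (1 of 19, 3 adjusted over the list alone, -1.81, 7.93e-11) were lower as well. Higher were the megakaryocyte list (2 of 13, 6 adjusted over the list alone, median 1.22, adjusted p = 1.20e-11), with Tubb1 and Pf4 (1.98 ± 0.48), the erythroid list (2 of 18, 5 adjusted over the list alone, 0.80, 6.89e-08), with Gata1 and Nfe2 (1.80 ± 0.41), the pan-hematopoietic list (1 of 19, 5 adjusted over the list alone, 0.84, 3.51e-07) and the hematopoietic transcription factors (2 of 23, 6 adjusted over the list alone, 0.81, 1.01e-05), of which Gfi1 was lower (-3.69 ± 0.75). Those 13 lists held with the estimated correlation. The epithelial (adjusted p = 0.387 with the estimated correlation), lateral plate (0.0846), hypoxia (0.359) and sarcomere lists (0.612) did not, and for the lateral plate and hypoxia lists the median (0.03 and 0.21) and the test and mean (-0.90 and -0.44) differed in sign. The lateral plate median was below 0, at -0.01 and -0.07, after cyclic loess and housekeeping centring.

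limma called 342 genes between these populations, 37 higher and 305 lower in CD41+ c-kit+ cells, or 20 and 323 after housekeeping centring. In the 6 arrays alone there were 1067 (161 higher and 906 lower), 333 of them shared. Without CD31+ replicate 1 there were 138, without CD31+ replicate 2 there were 152, without CD41+ replicate 1 there were 174 and without CD41+ replicate 2 there were 223. Tubb1, Gata1, Syne3, Tmem204 and Clec14a kept their call in each.

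Among Pdgfra- CD31+ yolk sac cells, those of Scl-/- embryos again had higher sarcomere transcripts. Actc1, cardiac alpha-actin, rose by 7.55 ± 1.23 (from 3.19 ± 0.02 to 10.75 ± 0.85), Myh7 by 6.73 ± 1.03, Chchd6, a protein of mitochondrial cristae, by 6.60 ± 1.06, Tnnt2 by 6.06 ± 0.91 and Myl7 by 5.96 ± 0.71. Lower were Gja5, a gap-junction protein of arteries (-5.35 ± 0.94), the lipoxygenase Alox12 (-4.08 ± 0.82), the platelet granule protein Rab27b (-3.91 ± 0.68), the polarity protein Pard6b (-3.73 ± 0.63) and the cytokine receptor Osmr (-3.58 ± 0.66). Adjusted p-values were 0.00256 to 0.0449. Another probe set of Chchd6 (0.16), Tnnt2 (0.05), Alox12 (-0.17) and Osmr (-0.39) moved the same way but hardly changed. Tnnt2 was 4.92 ± 3.22 in wild type. Pdgfra was higher in this gate by 3.71 ± 0.65 (adjusted p = 0.0194), with 2 of its 3 probe sets in that direction. The 2 sorts thus differed in the gate gene itself, so the sarcomere rise cannot be assigned to cells without Pdgfra. Of 22 sarcomere genes 6 were higher (9 adjusted over the list alone, median 2.26, adjusted p = 3.18e-16). Arterial and Notch genes were lower (2 of 18, 4 adjusted over the list alone, median -0.52, adjusted p = 0.000148), with Gja4 (-2.57 ± 0.44) beside Gja5, and cushion genes were higher (2 of 20, 3 adjusted over the list alone, 0.72, 0.000432), with Tgfb2 (3.67 ± 0.56) and Vcan (3.60 ± 0.61). These 3 lists held with the estimated correlation. The calls of the other 7 were lost: myeloid (median -0.48, adjusted p = 0.13 with the estimated correlation), with Tyrobp at -3.32 ± 0.52, megakaryocyte (-0.67, 0.0549), epithelial (-1.35, 0.257), visceral endoderm (-0.51, 0.393), pan-endothelial (-0.70, 0.29), cardiac transcription factors (0.37, 0.132) and cell cycle (0.26, 0.182).

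limma called 73 genes here, 50 higher and 23 lower in Scl-/-, or 31 and 36 after housekeeping centring, and 0 with the 6 arrays of this set alone, where 1664 genes had an unadjusted p under 0.05. Leaving out an array gave 221 genes without wild-type replicate 1, 128 without wild-type replicate 2, 125 without Scl-/- replicate 1 and 9 without Scl-/- replicate 2. Myl7 was the only one of the 10 named genes called in each. The 2 yolk sac comparisons of genotype have no arrays in common. They shared 7 higher genes (0.1 expected from independent lists), namely Myl7, Myh7, Tnnt2, Tnni1, Myl4, Kcnj8 and Sh3bgr, and 2 lower genes (0.1 expected), Tyrobp and Fcer1g. Of these, Tnni1, Myl4 and Sh3bgr were named after their values were seen. Both comparisons use the same spread of a gene, so their calls are not independent and the expected numbers are only a guide. With the arrays of each set alone 0 genes were shared. Across all genes, which are not independent replicates, the 2 sets of fold changes correlated little (Pearson's r 0.13 and Spearman's rho -0.01).

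**Figure D2:**
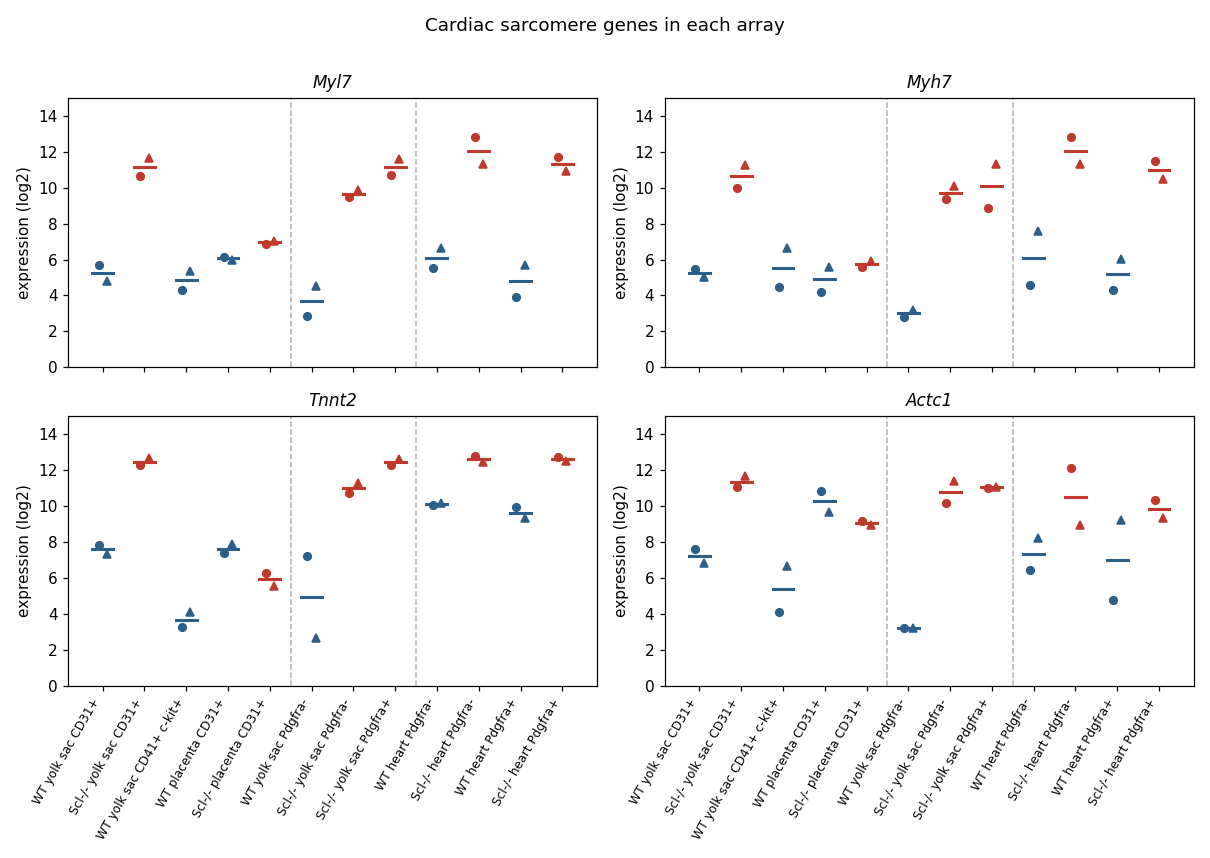
Expression (log2, vertical axes) of the sarcomere genes Myl7, Myh7, Tnnt2 and Actc1 in the 24 arrays, with circles and triangles for replicates 1 and 2, bars for group means, blue for wild type, red for Scl-/-, and dashed lines between the 3 separately normalized sets. Myl7 averages 11.14 in Scl-/- and 5.25 in wild-type yolk sac CD31+ cells, and 6.95 against 6.08 in placenta, where it did not pass the test.

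The Pdgfra+ CD31+ cells of the Scl-/- yolk sac, a population with no wild-type counterpart in the series, were compared with wild-type Pdgfra- cells. They combined a cardiac and mesenchymal profile with low endothelial transcripts. Actc1 was higher by 7.84 ± 1.23, the slow troponin Tnni1 by 7.65 ± 0.53 (from 3.40 ± 0.11 to 11.05 ± 0.49), Tnnt2 by 7.52 ± 0.91, Myl7 by 7.45 ± 0.71 and the sphingosine phosphate receptor S1pr3 by 7.43 ± 1.12. Gimap4, a GTPase of lymphoid and endothelial cells, changed by -6.91 ± 0.51, the mannose receptor Mrc1 by -6.84 ± 1.33, the tight-junction protein Cldn5 by -6.34 ± 0.82, the endothelial receptor Gpr182 by -6.32 ± 0.59 and the hyaluronan receptor Lyve1 by -6.28 ± 1.09. Adjusted p-values were 5.74e-06 to 0.00974. Pan-endothelial genes were lower in 15 of 22 cases (19 adjusted over the list alone, median -2.48, adjusted p = 1.01e-22), also Sox18 (-5.93 ± 0.98) and Esam (-5.80 ± 0.82). Sarcomere genes were higher in 8 of 22 cases (13 adjusted over the list alone, median 2.40, adjusted p = 1.59e-17) and cardiac transcription factors in 7 of 19 (10 adjusted over the list alone, median 1.85, adjusted p = 1.07e-10), with Myocd (6.04 ± 0.96), Tbx5 (4.35 ± 0.73), Gata5 (4.18 ± 0.55) and Hand2 (3.80 ± 0.72). Matrix genes (5 of 17, 8 adjusted over the list alone, median 2.12, adjusted p = 1.61e-08), with Col3a1 (6.48 ± 1.15), cushion genes (7 of 20, 9 adjusted over the list alone, 1.07, 1.01e-05), with Tgfb2 (5.43 ± 0.56), and smooth muscle genes (3 of 12, 6 adjusted over the list alone, 1.43, 3.22e-05), with Des (3.98 ± 0.77), were higher too. These 6 lists held with the estimated correlation. Lost were the calls of the myeloid (median -0.56, adjusted p = 0.109 with the estimated correlation), megakaryocyte (-0.53, 0.0623), epithelial (-1.69, 0.359), hematopoietic transcription factor (-0.49, 0.0557), arterial (-0.84, 0.109), venous (-1.25, 0.353) and cardiac excitation lists (0.41, 0.102), the latter with Ryr2 at 3.15 ± 0.37.

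limma called 506 genes in this contrast, 281 higher and 225 lower, or 195 and 402 after housekeeping centring, and 158 with the 6 arrays alone (105 and 53), of which 129 are shared. Of the 10 genes with the largest changes all but Tnnt2 stayed called with the 6 arrays alone. Tbx5, Gata5, Col3a1 and Esam did not. Without wild-type replicate 1 there were 608 genes, without wild-type replicate 2 there were 361, without Scl-/- replicate 1 there were 357 and without Scl-/- replicate 2 there were 201, and the 10 named genes other than Mrc1 were called in each.

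Within the Scl-/- yolk sac, Pdgfra+ cells differed from Pdgfra- cells in endothelial, cardiac transcription factor and matrix transcripts. Lum was higher by 5.89 ± 1.12, Ccdc141 by 4.82 ± 0.95, Shisa2 by 4.68 ± 0.91, the zinc finger protein Bnc2 by 4.64 ± 0.64 and the neuropeptide receptor Npy1r by 4.27 ± 0.63 (1 of its 2 probe sets). Cldn5 changed by -5.15 ± 0.82, the endothelial factor Sox18 by -5.0 ± 0.98, Gpr182 by -4.90 ± 0.59, Myzap by -4.87 ± 0.72 and Ldb2 by -4.78 ± 0.97, with adjusted p-values of 0.00216 to 0.0374 for the 10. Kit was also lower (-2.55 ± 0.44, adjusted p = 0.0143) and Pdgfra higher (3.05 ± 0.65, 0.0495) in Pdgfra+ cells. Of 22 pan-endothelial genes 7 were lower (17 adjusted over the list alone, median -1.70, adjusted p = 1.04e-28). Cardiac transcription factors were higher (2 of 19, 9 adjusted over the list alone, median 1.75, adjusted p = 4.16e-10), with Gata5 (3.75 ± 0.55), as were matrix genes (1 of 17, 7 adjusted over the list alone, 1.48, 2.50e-09) and smooth muscle genes (0 of 12, 1 adjusted over the list alone, 1.31, 0.00034). These 4 lists held with the estimated correlation. Of the sarcomere genes 0 of 22 passed the test (2 adjusted over the list alone, median 0.42, adjusted p = 0.0112, and 0.498 with the estimated correlation). The venous (median -0.88, adjusted p = 0.105 with the estimated correlation), cushion (0.81, 0.154), visceral endoderm (0.17, 0.468) and cardiac excitation lists (0.25, 0.0957) lost their calls as well.

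limma called 108 genes, 47 higher and 61 lower in Pdgfra+ cells, and 0 with the 6 arrays alone, where 1283 had an unadjusted p under 0.05. Leaving out Pdgfra+ replicate 2 left 37 genes and Pdgfra- replicate 2 left 45, while 124 and 130 were called without replicate 1 of the Pdgfra+ and Pdgfra- cells. Bnc2 and Gpr182 were called in each of these fits.

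In the heart, Pdgfra+ CD31+ cells from libraries labelled Scl-/- had higher transcripts of the response to low oxygen and of cardiac transcription factors than wild-type cells, as lists, and lower endothelial ones. Vldlr, the very low density lipoprotein receptor, was higher by 8.23 ± 1.34, Myl7 by 6.49 ± 0.71 (from 4.80 ± 1.24 to 11.30 ± 0.57), Vsnl1, a neuronal calcium sensor, by 6.44 ± 0.82, Timm10b by 6.22 ± 0.95 and Hoxa3 by 6.17 ± 1.17. Ddx31 changed by -5.99 ± 0.84, Cavin1 and Ehd2, proteins of caveolae, by -5.76 ± 0.89 and -5.52 ± 0.52, Fry by -4.79 ± 0.88 and Emcn, an endothelial sialomucin, by -4.78 ± 0.82. Adjusted p-values were 0.000171 to 0.0158, and at least 1 other probe set of Timm10b, Hoxa3, Ddx31, Ehd2 and Fry did not move the same way. For Cavin1 another probe set hardly changed (-0.05). Of 19 hypoxia and glycolysis genes 5 were higher (15 adjusted over the list alone, median 1.73, adjusted p = 8.96e-18), among them Ankrd37 (3.78 ± 0.86) and the peptide hormone Adm (3.45 ± 0.58). Cardiac transcription factors were higher (2 of 19, 5 adjusted over the list alone, median 0.79, adjusted p = 1.98e-05), with Hopx (4.35 ± 0.70) and Tbx18 (3.00 ± 0.65), and pan-endothelial genes lower (3 of 22, 8 adjusted over the list alone, median -1.10, adjusted p = 2.58e-06), with Icam2 (-2.98 ± 0.44). These 3 lists held with the estimated correlation. The sarcomere list (4 of 22 higher, 6 adjusted over the list alone, median 0.78) lost its call (adjusted p = 0.178 with the estimated correlation), although Myh7 (5.83 ± 1.03) and Myl4 (3.99 ± 0.65) passed the test. Lost too were the immediate early (median -0.96, adjusted p = 0.359 with the estimated correlation), matrix (-0.49, 0.268) and cardiac excitation lists (0.06, 0.127), the last with a median of -0.13 after housekeeping centring and with Ryr2 at 4.04 ± 0.37.

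In Pdgfra- heart cells the same contrast gave Myl7 (5.97 ± 0.71, from 6.08 ± 0.77 to 12.05 ± 1.06), Myh7 (5.95 ± 1.03), the kinesin Kif26b (5.66 ± 0.92), the metallothionein Mt1 (5.45 ± 0.69) and Sh3bgr (5.16 ± 0.66) as the largest rises. Gja5 (-5.14 ± 0.94), Ldb2 (-4.80 ± 0.97), Nipal4 (-4.49 ± 0.86), Rai2 (-4.46 ± 0.64) and the innate receptor Tlr3 (-4.42 ± 0.83) were the largest falls, with 1 of 2 probe sets each for Nipal4 and Tlr3. Adjusted p-values were 0.00115 to 0.0369. Another probe set of Mt1 (0.43) and of Sh3bgr (0.34) hardly changed. Pdgfra changed by 2.33 ± 0.65 in this gate and did not pass the test (adjusted p = 0.168). The 2 sorts may thus differ in the gate gene itself. Hypoxia and glycolysis genes were higher as a list here too (2 of 19, 7 adjusted over the list alone, median 1.21, adjusted p = 2.84e-11), with Bnip3, a mitophagy receptor (4.22 ± 0.72). So were cardiac transcription factors (1 of 19, 3 adjusted over the list alone, 1.02, 0.000284), with Hopx (5.09 ± 0.70), and the cardiac excitation list (1 of 19, 2 adjusted over the list alone, 0.34, 0.00215), with Ryr2 (2.74 ± 0.37). These 3 held with the estimated correlation. The sarcomere list (3 of 22 higher, 7 adjusted over the list alone, median 1.98, adjusted p = 5.35e-11) reached 0.0674 as an adjusted p with the estimated correlation. The pan-endothelial (median -0.74, adjusted p = 0.0749 with the estimated correlation), immediate early (-0.44, 0.359) and cell cycle lists (-0.31, 0.178) lost their calls.

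These 2 heart contrasts gave 299 genes (154 higher and 145 lower, or 107 and 192 after housekeeping centring) in Pdgfra+ cells and 88 genes (38 and 50) in Pdgfra- cells. The 8 heart arrays alone called 0 and 1 (Gja5), with 1241 and 853 genes at an unadjusted p under 0.05. Single genes are therefore weakly supported in the heart. In simulated arrays over 50% of the calls of the larger fit were unchanged genes, a share that need not hold for the real calls. Without each array, Pdgfra+ cells gave 393 and 329 genes (replicates 1 and 2 labelled Scl-/-) and 1067 and 353 (wild-type replicates 1 and 2), and Pdgfra- cells gave 206, 190, 220 and 52 in the same order. The 2 arrays labelled Scl-/- with Tal1 at the wild-type level were left out together as an alternative chosen after seeing the data. Each gate then has 1 array labelled Scl-/-, and this lone array is assumed to vary like the other groups. The counts were then 533 in Pdgfra+ and 249 in Pdgfra- cells, and the hypoxia medians 1.86 and 1.66. Both were still called with the estimated correlation. So were the cardiac transcription factors in both gates. The call of the pan-endothelial list in Pdgfra+ cells was lost (median -0.88, adjusted p = 0.228 with the estimated correlation), as was that of the cardiac excitation list in Pdgfra- cells (0.33, adjusted p = 0.0546 with the estimated correlation). The sarcomere list in Pdgfra- cells then passed (median 3.35, adjusted p = 0.00764 with the estimated correlation), but not in Pdgfra+ cells (0.74, adjusted p = 0.162 with the estimated correlation). Genotype effects differed between the heart gates for 22 genes (13 higher in Pdgfra+ cells and 9 lower), and between Pdgfra- cells of yolk sac and heart for 25 (17 and 8).

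Sorting on Pdgfra separated heart cells in their endothelial transcripts. In wild-type hearts, Pdgfra+ cells had higher Tubb3, a neuronal tubulin (6.17 ± 1.15), Kif26b (5.90 ± 0.92), Esrrg, an orphan nuclear receptor (5.73 ± 0.78), the collagen Col1a1 (5.44 ± 0.96) and Papss2 (5.25 ± 1.06), and lower Hoxa3 (-7.28 ± 1.17), Entpd1 (-5.36 ± 1.08), the adhesion receptor Icam1 (-5.22 ± 0.97), Srd5a3 (-4.97 ± 1.05) and Nkrf (-4.95 ± 0.73), where another probe set of Esrrg, Hoxa3 and Nkrf did not move the same way. Adjusted p-values were 0.00402 to 0.0473. Another probe set of Srd5a3 hardly changed (-0.25). Hoxa3 (2.87 ± 0.28 in wild-type Pdgfra+ cells) and Kif26b (3.22 ± 0.42 in wild-type Pdgfra- cells) were also named by genotype, through the same wild-type arrays. Pdgfra was higher (3.42 ± 0.65, adjusted p = 0.0276, 2 of 3 probe sets) and Kit lower (-2.16 ± 0.44, 0.0407). The pan-endothelial list was lower (1 of 22, 8 adjusted over the list alone, median -1.09, adjusted p = 4.85e-10), with Kdr (-2.26 ± 0.44), and held with the estimated correlation. The calls of 6 lists did not: hypoxia (median -0.80, adjusted p = 0.0865 with the estimated correlation), venous (-1.04, 0.115), cushion (1.69, 0.0737), with Twist1 (2.84 ± 0.54), arterial (-0.72, 0.066), matrix (0.75, 0.21) and cardiac transcription factors (0.60, 0.189). In libraries labelled Scl-/-, Pdgfra+ cells had higher Vsnl1 (4.13 ± 0.82), Zcchc7 (3.83 ± 0.78), Kif13a (3.82 ± 0.73), the retinoic acid binding protein Crabp2 (3.78 ± 0.81) and Ppp1r14a (3.65 ± 0.58), and lower Tmem204 (-7.72 ± 0.95), the lectin Clec1b (-6.45 ± 0.81), the apelin receptor Aplnr (-5.87 ± 0.74), Exoc6 (-5.75 ± 0.55) and Uxt (-4.96 ± 0.99), where another probe set of Zcchc7, Kif13a and Exoc6 did not move the same way. Adjusted p-values were 0.000226 to 0.0432. Pan-endothelial genes were again lower (4 of 22, 13 adjusted over the list alone, median -1.38, adjusted p = 2.14e-15), with Icam2 (-3.46 ± 0.44), and cardiac transcription factors higher (0 of 19 in either adjustment, 0.94, 0.000345), both with the estimated correlation too. The latter was not called without Pdgfra- replicate 2. The venous list (median -0.64, adjusted p = 0.0959 with the estimated correlation) and the oxidative phosphorylation list (-0.20, 0.272) lost their calls.

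The 2 gate contrasts called 110 genes in wild-type hearts (33 higher and 77 lower in Pdgfra+ cells, 35 and 43 after housekeeping centring, 48 and 65 after cyclic loess) and 142 in libraries labelled Scl-/- (34 and 108). The 8 heart arrays alone called 0 in both, with 1152 and 926 genes at an unadjusted p under 0.05. In simulated arrays 54.9% and 49.8% of the calls of the larger fit were unchanged genes, shares that need not hold for the real calls. Wild-type counts were 1014 and 191 without Pdgfra+ replicates 1 and 2, and 195 and 37 without Pdgfra- replicates 1 and 2, and the counts labelled Scl-/- were 233, 215, 283 and 173 in that order. Esrrg was called in each wild-type fit, and Ppp1r14a, Tmem204, Clec1b, Aplnr and Exoc6 in each of the others.

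**Figure D3:**
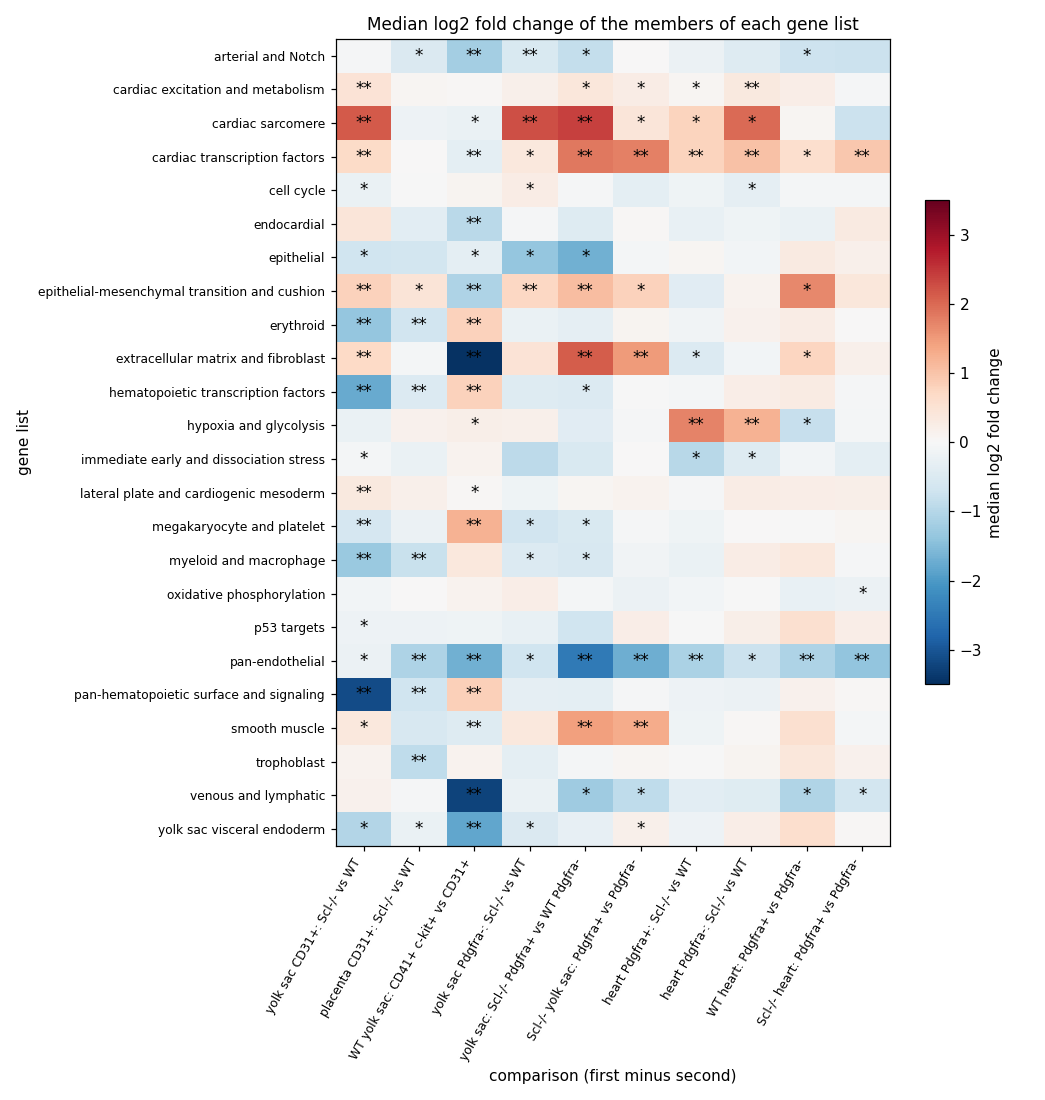
Median log2 fold change of the measured members of each of the 24 gene lists (rows) in each of the 10 comparisons (columns), red where the first group named is higher and blue where it is lower, with 1 star for an adjusted p under 0.05 by camera and a pair of stars where the call holds with an estimated correlation. Sarcomere genes have medians of 2.16 and 2.26 in the 2 yolk sac comparisons of genotype, and hypoxia genes of 1.73 and 1.21 in the 2 heart comparisons.

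**Figure D4:**
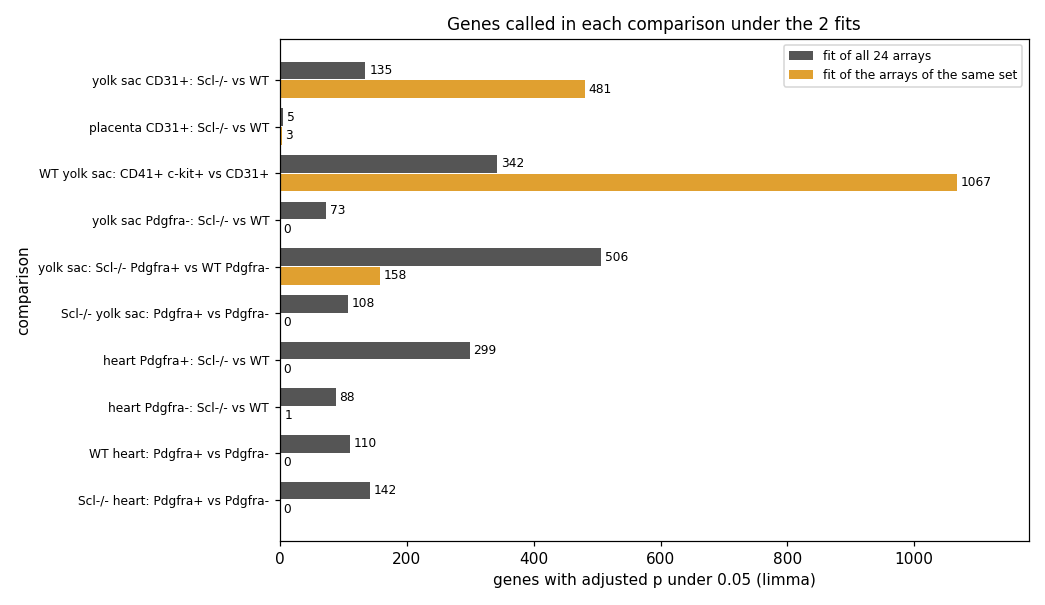
Number of genes with an adjusted p under 0.05 (limma, horizontal axis) in each of the 10 comparisons, in the fit of all 24 arrays (grey) and in the fit of the arrays of the same set (orange). The count goes from 135 to 481 in yolk sac CD31+ cells by genotype and from 299 to 0 in Pdgfra+ heart cells by genotype.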

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

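The explanations weighed here, their tests and the tests of gene lists for differences between tissues were chosen after the results had been seen. The results named are those where the effect of genotype differs between 2 tissues or 2 gates by a test of the difference itself (limma, adjusted p under 0.05 over 18193 genes). Between yolk sac and placenta CD31+ cells the effect differed for 10 genes, 3 higher in yolk sac and 7 lower (2 and 1 of 3 with housekeeping centring, 1 and 0 with quantile normalization). The fit of the 10 arrays alone gave 7 with the opposite split, 6 higher and 1 lower. Without wild-type yolk sac replicates 1 and 2 there were 0 and 0, with 501 genes at an unadjusted p under 0.05 in the fit of all 24 arrays, without Scl-/- yolk sac replicates 1 and 2 there were 3 and 1, and without placenta replicates 1 and 2 there were 62 and 4 (wild type) and 17 and 2 (Scl-/-). The differences, yolk sac minus placenta, are Rbm24 5.02, Tecrl 4.20, Rassf6 3.67, Tyrobp -4.71, Rgs18 -4.09, Sla -3.94, Fcer1g -3.52 and Il18rap -3.35.

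Between the Pdgfra+ and Pdgfra- heart gates the effect of the label Scl-/- differed for 22 genes, 13 higher and 9 lower in Pdgfra+ cells (5 and 8 with housekeeping centring), and limma called 0 with the 8 heart arrays alone, where 790 had an unadjusted p under 0.05. Leaving out an array gave 109, 70, 117 and 66 genes (Pdgfra+ replicates 1 and 2 and Pdgfra- replicates 1 and 2 labelled Scl-/-) and 465, 59, 119 and 13 (the wild-type arrays in that order), and 136 without the 2 arrays labelled Scl-/- that have Tal1 at the wild-type level. The differences are Zfp772 7.38, Zcchc7 6.55, Pcdh7 6.23, Ints13 5.02, Rai2 4.98, Tmem179 -7.09, Nars2 -6.59, Nup214 -6.07, Rorb -5.26 and Exoc6 -5.02. Between the gates labelled Scl-/-, another probe set of Zcchc7 and of Exoc6 moved the other way. Rai2 lies on chromosome X, and the mix of male and female embryos differed with the label in the heart. Zfp772, Pcdh7 and Rorb kept their call without each array.

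Between Pdgfra- cells of yolk sac and of heart the effect differed for 25 genes, 17 higher and 8 lower in yolk sac (15 and 13 with housekeeping centring), and for 3 when only arrays of these sets were fitted. Leaving out an array gave 89 and 52 genes (wild-type yolk sac replicates 1 and 2), 47 and 7 (Scl-/- yolk sac), 123 and 81 (heart labelled Scl-/-) and 55 and 16 (wild-type heart), and 100 without the 2 heart arrays named above. The differences are Col26a1 7.76, Ate1 6.48, Cog7 6.0, Zfp772 5.88, Trp53i11 5.85, Pard6b -5.30, Rorb -5.30, Acrbp -4.07, Ptprj -4.02 and Lifr -3.91. Zfp772 and Rorb were also named between the heart gates. Both tests use the genotype change in Pdgfra- heart cells, -4.38 for Zfp772 and 5.13 for Rorb, so they are not independent results. Ate1 and Rorb kept their call without each array and with the arrays of these sets alone.

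Sarcomere genes were higher in Scl-/- yolk sac CD31+ cells. If the Scl-/- sort merely held fewer blood cells, pan-endothelial genes would be higher too. The median change of sarcomere genes exceeded that of pan-endothelial genes by 2.35, so the 2 lists did not move together. The p-value was 1e-05, the smallest that 100000 permutations of genes can give, and genes are not independent replicates. This p-value decides nothing, because the sarcomere list was picked for its rise and both medians were known. The pan-endothelial list also holds the gate gene Pecam1, and Erg, which stands in the hematopoietic transcription factor list too. Still, the pan-endothelial median was below 0 and the sarcomere median lay 2.35 above it. For these 2 lists this argues against a smaller share of blood cells as the only cause of the sarcomere rise. A smaller share beside another cause is not excluded. Cardiomyocytes carried into the sort remain possible: 22 of 22 measured sarcomere genes had a change above 0, and a program switched on within CD31+ cells would look the same, so these data cannot tell.

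Hypoxia and glycolysis genes were higher in both heart gates labelled Scl-/-. In the Scl-/- yolk sac CD31+ pair, whose arrays differ in Xist, the list lay at -0.34 (Xist-low minus Xist-high) and in the Scl-/- placenta pair at 0.23, but with 1 array each this cannot exclude an effect of embryo sex. Low oxygen throughout the embryo could also raise the list. Its change in Pdgfra- cells differed by -1.23 between yolk sac and heart (camera adjusted p = 0.000122, and 0.102 with the estimated correlation). The list was not called for genotype in yolk sac CD31+, placenta CD31+ or Pdgfra- yolk sac cells. A list that is not called may still have changed, so this cannot be told. Without the arrays labelled Scl-/- with Tal1 at the wild-type level the smaller median was 1.66 (adjusted p = 1.66e-07, and 0.0299 with the estimated correlation), but each gate then has 1 array labelled Scl-/-, assumed to vary like the other groups, so a share of these arrays in the difference stays open.

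Blood surface and signaling genes were reduced less by loss of Scl in placenta than in yolk sac (median difference -1.90, adjusted p = 3.06e-25, and 0.000779 with the estimated correlation). The list lay lower in wild-type placenta than in wild-type yolk sac by a median of -1.44 (p = 2.11e-24, and 3.7e-05 with the estimated correlation), but this is part of the pattern itself, so a smaller share of blood cells in that sort stays open. Maternal blood cells in the placenta would raise the list in Scl-/- placenta over Scl-/- yolk sac. There the median difference was 0.43 (camera p = 0.0162, and 0.161 with the estimated correlation), so this cannot be told. Tal1 was also higher in Scl-/- placenta (5.32 and 5.06) than in Scl-/- yolk sac CD31+ cells (3.24 and 2.91). Maternal cells could give this too, but the cause was not tested. The 3 embryonic globins, which are not in the list, differed by 0.44 in Scl-/- and by only -0.38 in wild type between the same tissues.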

How the results depend on the processing

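The alternatives were planned before the data were examined, except the log2 of the deposited values, the heart arrays left out for their Tal1 level, the array weights, the genes of chromosomes X and Y and the lists without the 2 members read as another gene, which were chosen after seeing the data. Of 250 results for named genes, all alternatives together gave 3192 values, 2475 of them on the same side of the threshold, and of 101 called lists 1515 values, 1304 of them on the same side. With the arrays of the same set alone, 102 gene results stayed and 148 became weaker, against 92 and 9 for lists. With the estimated correlation 52 lists stayed and 49 became weaker, and with fry 74 and 27. Without each array in turn, where the lone array is assumed to vary like the other groups, 711 gene results stayed, 9 reversed and the others became weaker. The 2-fold threshold changed no count. Signal over background limits dim genes, and 14196 genes were left after the filter. Where a cause is not named the cause was not tested.

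Genes called for genotype in placenta (5) were 8 with quantile normalization, 10 with cyclic loess and 10 with the mean of all probe sets. The difference between yolk sac and placenta (10 genes) was 1 with quantile normalization, 6 with cyclic loess, 3 with housekeeping centring, 6 with the mean of probe sets, 5 without dim genes and 1 with array weights, and that between heart gates (22) 13 with housekeeping centring. With the arrays of the same set alone, which have fewer residual degrees of freedom, the counts were 481 in yolk sac CD31+, 3 in placenta, 1067 for CD41+ c-kit+, 0 for Pdgfra- yolk sac, 158 and 0 for Scl-/- Pdgfra+ yolk sac against wild-type and Scl-/- Pdgfra- cells, and 0 and 1 for genotype in Pdgfra+ and Pdgfra- heart (limma, 1664, 1283 and 1241 genes at an unadjusted p under 0.05 for the counts of 0). They were 0 and 0 for the heart gates in wild type and in libraries labelled Scl-/- (1152 and 926 unadjusted), 0 for the difference between heart gates (790 unadjusted), 3 between Pdgfra- cells of the 2 tissues and 0 shared between the 2 yolk sac genotype comparisons. The mean of probe sets gave 8 genes shared by yolk sac and placenta and 14 by the 2 yolk sac comparisons, against 2 and 14 with array weights. Array weights also gave 318 genes in yolk sac CD31+, 2 in placenta, 911 for CD41+ c-kit+, 54 for the heart gates in wild type and 334 in libraries labelled Scl-/-. The log2 of the deposited values gave 229 genes in yolk sac CD31+, 50 in placenta, 646 for CD41+ c-kit+ and 24 for the difference between the tissues. Without the heart arrays labelled Scl-/- with Tal1 at the wild-type level there were 533 and 249 for genotype in Pdgfra+ and Pdgfra- heart, 265 for the gates labelled Scl-/-, and 136 and 100 for the 2 differences that use them, where the lone array left in each gate is assumed to vary like the other groups. Lists passing with the estimated correlation numbered 11 in yolk sac CD31+, 3 in Pdgfra- yolk sac, 6 and 4 for Scl-/- Pdgfra+ yolk sac against wild-type and Scl-/- Pdgfra- cells, 3 and 3 for genotype in Pdgfra+ and Pdgfra- heart, and 1 and 2 for the gates. With fry 6 passed in Pdgfra- yolk sac and 4 in Pdgfra+ heart.

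With the replicate number as a block, the counts were 135 in yolk sac CD31+, 4 in placenta, 315 for CD41+ c-kit+, 54 for Pdgfra- yolk sac, 474 and 73 for Scl-/- Pdgfra+ yolk sac, 218 and 81 for genotype in Pdgfra+ and Pdgfra- heart, 95 and 78 for the gates, and 3, 12 and 13 for the 3 differences. The block keeps 197 gene results and weakens 53, and whether arrays with the same number come from the same embryos is not given in the sources used here. The differences of same-numbered arrays from their group means correlated at -0.02 to 0.15 in the heart, 0.04 to 0.13 in the Pdgfra-sorted yolk sac, -0.01 to 0.05 in the yolk sac CD31+ and CD41+ groups and 0.3 in placenta.

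Leaving out 1 array at a time gave 50 to 70 genes in yolk sac CD31+, 8 to 63 in placenta, 138 to 223 for CD41+ c-kit+, 9 to 221 in Pdgfra- yolk sac, 201 to 608 and 37 to 130 for Scl-/- Pdgfra+ yolk sac against wild-type and Scl-/- Pdgfra- cells, 329 to 1067 and 52 to 220 for genotype in Pdgfra+ and Pdgfra- heart, and 37 to 1014 and 173 to 283 for the gates in wild type and in libraries labelled Scl-/-. The differences ranged from 0 to 62 (yolk sac and placenta), 13 to 465 (heart gates) and 7 to 123 (Pdgfra- cells), and the shared genes from 3 to 12 in both comparisons. Lists ranged from 5 to 11 in placenta, 4 to 7 and 4 to 8 for genotype in Pdgfra+ and Pdgfra- heart, and 4 to 8 for the gates in wild type. Tal1, which did not pass the test there, changed sign between Scl-/- yolk sac gates (0.11 without Pdgfra+ replicate 2, range -0.62 to 0.11), between the gates labelled Scl-/- in heart (-1.98 without Pdgfra+ replicate 1 and -0.80 without Pdgfra- replicate 1, highest 2.28), for genotype in Pdgfra+ heart (1.63 without replicate 2 labelled Scl-/- and 0.17 without wild-type replicate 1, lowest -2.63) and Pdgfra- heart (0.59 without replicate 1 labelled Scl-/- and 0.22 without wild-type replicate 1, lowest -1.31), and between wild-type heart gates (-0.38 without Pdgfra+ replicate 1 and -0.29 without Pdgfra- replicate 2, highest 0.97). The epithelial list in Pdgfra- yolk sac cells had a median of -0.25 without wild-type replicate 1, where the test did not pass and its direction was opposite, and -2.91 without wild-type replicate 2.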

Other observations

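The tests of lists for differences between tissues and gates given here were chosen after the results had been seen. Of 72 such tests 24 passed, and 6 of these passed with the estimated correlation, all between yolk sac and placenta CD31+ cells. The change with loss of Scl was more positive in yolk sac than in placenta for the sarcomere list (median difference 2.52, adjusted p = 3.71e-19, and 0.0378 with the estimated correlation), which was not called in placenta (median -0.17, adjusted p = 0.483). It was more negative in yolk sac for the hematopoietic transcription factors (median difference -1.33, adjusted p = 1.29e-14, and 0.000434 with the estimated correlation), the myeloid list (-1.54, 3.22e-11 and 0.0255), the megakaryocyte list (-0.69, 3.01e-05 and 0.0378) and the erythroid list (-0.49, 0.000112 and 0.0388).

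Transcripts of the sex chromosomes varied between arrays of a group. In the yolk sac CD31+ cells of Scl-/- embryos Xist was 3.87 in replicate 1 and 11.55 in replicate 2, with Kdm5d at 9.80 and 8.60. In Scl-/- placenta Xist was 6.58 and 12.30 and Kdm5d 9.48 and 3.52. In the Pdgfra-sorted Scl-/- yolk sac, Kdm5d was 7.83 and 7.48 in replicate 1 of the Pdgfra+ and Pdgfra- cells and 2.33 and 1.82 in replicate 2, so arrays of the same number share this pattern in that set, although their other differences from the group means correlated at only 0.13.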
